A study of Mus musculus with 6 samples.

How the data were processed

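Microglia, the resident macrophages of the brain, were sorted as CD11b-positive, CD45-low cells from the hippocampus of male mice between postnatal days 17 and 21, per the labels. The mice were wild type (WT) or carried 1 disrupted copy of Mll5, now called Kmt2e, a gene for a protein of the MLL family. There were 6 RNA-seq libraries, 3 per genotype, and the labels number the animals separately, so each library was taken as 1 mouse. Per the labels' protocols, RNA was extracted with TRIzol, cDNA was made and amplified by the SMART-seq method, and libraries were made with a transposase kit.

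The authors deposited 1 table of whole-number counts per gene symbol for the 6 libraries, with gene coordinates on the mouse build mm39. Per the submitters' processing notes, FastQC, STAR, StringTie and DESeq2 were used. Their versions, their order, the counting step and the strand setting are not given in the sources used here. The table lists 11881 genes, and each of them has a count in at least 2 libraries. Reads of overlapping, antisense or near-identical genes cannot be told apart in such counts. The reference annotation at hand is of another build, so coordinates come from the deposited table alone.

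Groups came from the labelled genotype. Genes were kept with filterByExpr by group (minimum count 10, minimum total count 15), which left 10832 genes and removed 1049. Library sizes were scaled by TMM, and CPM, counts at a common library size, use those sizes. The main test was edgeR's quasi-likelihood test with robust dispersions (edgeR 4.0.16, limma 3.58.1, R 4.3.3), labelled Mll5+/- minus labelled WT, with Benjamini-Hochberg adjustment and a threshold of 0.05. All p-values are two-sided, and those of single genes measure the spread between these libraries. SEs of log2 fold changes were taken from the fitted coefficient and its F statistic, and 95% intervals from the same. Where all libraries of a genotype were at 0, the values per library are given and no fold.

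The tests, the alternatives, 34 gene lists and the rule for named genes were fixed before the data were examined. Of the lists, 22 covered processes and 12 covered markers of other cell types, handling or RNA quality, and 29 had at least 5 tested members. They were tested with camera at a preset correlation of 0.01 between genes, adjusted over lists, and with an estimated correlation and fry as alternatives. Camera compares a list's genes with all other tested genes. At the preset correlation, its p leaves out most of the variation between libraries that a list's genes share. Named genes were Kmt2e, the genes of the pathway in the series title with their adaptor and nearest paralogs, 10 higher and 10 lower genes without overlap between genotypes and with a mean CPM of at least 1, and the members of smallest p of each list. As no gene passed the threshold, the 10 in each direction are those of smallest unadjusted p, and no predicted gene had to be passed over. Some genes that the rule names are left out of the text. For lists of markers and quality, the 3 members of highest mean CPM were looked at as well. Tmem119, Cx3cr1, Csf1r and Ddx3y were named outside the rule, as identity checks.

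The script was tested on simulated data with the measured dispersions, in which 200 genes were given known folds. The members of the lysosome list were raised 2-fold as well. With so many changed genes the adjustment is easier to pass than with few, so the shares recovered may overstate those in the real data. On 10317 simulated genes tested for this comparison, 0% of the 2-fold, 17.4% of the 4-fold, 43.8% of the 8-fold and 65.3% of the 16-fold changes passed the threshold, and 2 unchanged genes did. With 1% of the measured dispersion, 96.0% of the 2-fold changes passed.

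The alternatives were DESeq2 1.42.0, limma-voom with sample weights, DESeq2 size factors, total counts without TMM, other low-count filters, 1 surrogate variable (sva 3.50.0), library sizes without mitochondrial genes and the 20 most abundant genes, other thresholds and leaving out each library in turn. No library was left out of the main test. No pairs of libraries were formed, since the replicate numbers used here only follow the order of the samples. The deposited counts total between 21075570 and 29730400 per library, at which 3 counts correspond to between 0.104 and 0.142 CPM. Amplified reads without molecular identifiers are not independent molecules.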

Results

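Gene expression was measured in hippocampal microglia of 3 mice labelled WT and 3 mice labelled Mll5+/-, 1 library per mouse. The libraries labelled WT held 23884734, 25912809 and 29730400 counts, and those labelled Mll5+/- held 25247504, 28053173 and 21075570. Microglial transcripts were abundant in all 6 libraries. Tmem119 had 207 ± 12.1 CPM (SD, n = 3) in the libraries labelled WT and 226 ± 5.56 CPM (SD, n = 3) in those labelled Mll5+/-. Cx3cr1, the fractalkine receptor, had 1511 and 1342 CPM on average (libraries labelled WT first), and Csf1r, the receptor that microglia need for survival, had 935 and 925 CPM. The Y-linked gene Ddx3y had 871 ± 73.0 and 891 ± 118 CPM (SD, n = 3 each), as the labelled sex requires.

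Kmt2e (Mll5), on chromosome 5 from 23639439 to 23709233 (mm39), was looked at first, since 1 of its copies is disrupted in the heterozygous mice. Its level was 480, 378 and 688 CPM in the libraries labelled WT and 648, 298 and 513 CPM in those labelled Mll5+/-. The log2 fold change was -0.08 (SE 0.314, edgeR unadjusted p = 0.799), with a 95% interval from -0.79 to 0.63. The interval leaves out a loss of 1 on the log2 scale, so the whole-gene count did not show the loss of a copy, and genotypes are named throughout as the labels give them. The disrupted part of the gene is not given in the sources used here, and counts from a transcript with an altered part would not be told apart from intact ones.

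The series title names a pathway from TREM2 through SGK3 to GSK3-beta, and the first question was whether its genes differ between genotypes. Sgk3, which encodes a serine/threonine kinase of the SGK family, was the gene of smallest p among all 10832 tested. It lies on chromosome 1 from 9868332 to 9971070 and had 56.7 ± 1.46 CPM (SD, n = 3) in the libraries labelled WT against 12.1 ± 2.71 CPM (SD, n = 3) in those labelled Mll5+/-. Its paralog Sgk1 was also at a lower level in all 3 libraries labelled Mll5+/-, with 112 ± 51.6 against 215 ± 32.8 CPM (SD, n = 3 each). Trem2, a lipid-sensing surface receptor of microglia, and Tyrobp, its signalling adaptor, had overlapping levels.

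The log2 fold change of Sgk3 was -2.23 (SE 0.357, edgeR unadjusted p = 0.000166). It did not pass when adjusted over all genes in edgeR's test (smallest adjusted p of all genes 0.9995), and it passed in DESeq2 (adjusted p = 0.000111). Adjusted over the list alone, 1 of the 6 title genes passed, Sgk3 (edgeR adjusted p = 0.000996), and 0 passed over all genes tested. The study named this pathway from work that included these samples, so the count over the list alone is not independent evidence. Sgk1 had a log2 fold change of -0.94 (SE 0.363, edgeR unadjusted p = 0.0296). Trem2 had 0.23 (SE 0.254) and Tyrobp 0.56 (SE 0.324). Gsk3b, the kinase at the end of the named pathway, took 92.2, 63.1 and 1477 CPM in the libraries labelled WT and 57.5, 1526 and 1319 CPM in those labelled Mll5+/-, so that its log2 fold change of 0.83 had an SE of 1.75. Its paralog Gsk3a had 32, 41 and 0 counts in the libraries labelled WT and 12, 63 and 58 counts in those labelled Mll5+/-.

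**Figure D1:**
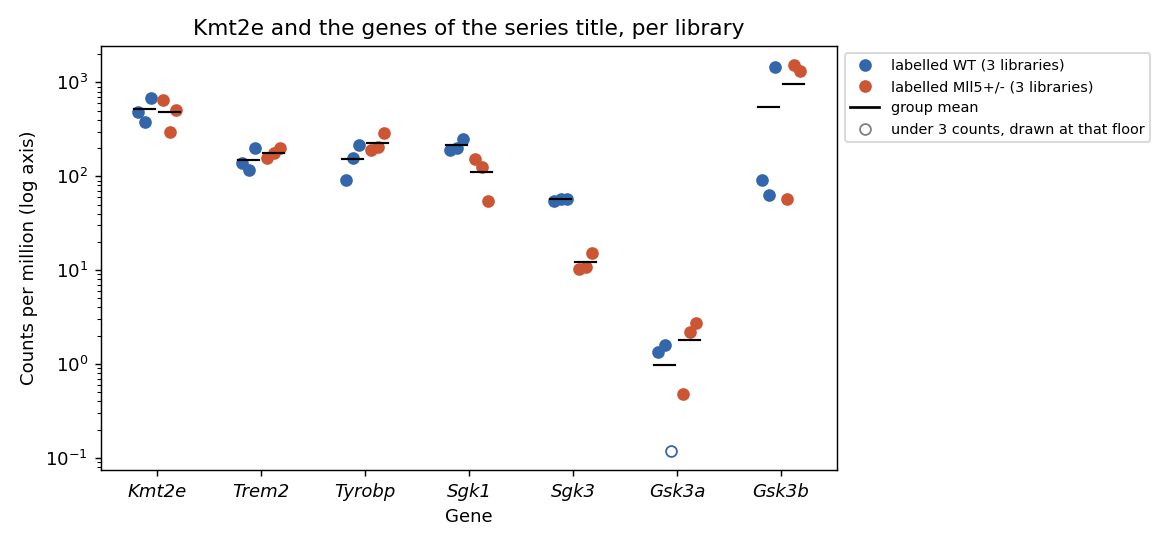
CPM on a log axis for Kmt2e and the genes of the title pathway, 1 point per library, with a bar at each group mean. Sgk3 had 56.7 CPM on average in the libraries labelled WT and 12.1 CPM in those labelled Mll5+/-, while the libraries of Gsk3b lie far apart within both genotypes.

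Across all genes, the libraries labelled Mll5+/- held higher levels of genes such as Anapc15, a subunit of the anaphase-promoting complex, and Ptbp3, a splicing regulator, and lower levels of Csmd3 and Mettl4. None of them passed the threshold in edgeR. Of a value against another, the mean of the libraries labelled Mll5+/- comes first. Anapc15 had 141 ± 43.3 against 51.9 ± 9.41 CPM and Ptbp3 had 225 ± 26.8 against 114 ± 28.8 CPM (SD, n = 3 each). Csmd3, which encodes a large transmembrane protein, had 38.6 ± 12.3 against 117 ± 16.1 CPM, and Mettl4, a methyltransferase gene, had 50.3 ± 4.35 against 99.7 ± 8.35 CPM (SD, n = 3 each).

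In edgeR's test 0 genes passed an adjusted p of 0.05, with 312 genes under an unadjusted p of 0.05 (147 higher and 165 lower), where 541.6 would be met by chance. DESeq2 was run on all 11881 listed genes, without the low-count filter. It called 29 genes, 11 higher and 18 lower, with 565 under an unadjusted p of 0.05. The chance count of 541.6 is for the 10832 filtered genes and does not apply to those 565. On the filtered genes, limma-voom called 0, with 467 under an unadjusted p of 0.05. Among the 29 genes were Sgk3, Csmd3, P2ry12, Gja1, Anapc15 and Tnpo3. Of the 29 genes, 13 were at 0 in all libraries of 1 genotype, 7 had overlapping genotypes and 5 were not tested in edgeR. Levels of 1010 genes (9.32%) did not overlap between the genotypes, where chance gives 10%. The biological coefficient of variation was 80.4%.

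The other genes of smallest p in the direction of higher levels were Rere, Tmem19, Aldh1l2, Tnpo3, Cinp, Selenoi, Septin9 and Zkscan2. Rere, a transcriptional corepressor gene, had 34.9 against 8.75 CPM, Tmem19 had 33 against 5.92 CPM, and Cinp had 37.7 against 10.4 CPM. Selenoi, a phospholipid synthesis enzyme, had 116 against 57.2 CPM. Tnpo3, a nuclear import receptor, had 181, 175 and 24.6 CPM in the libraries labelled Mll5+/- against at most 20.1 CPM in those labelled WT. Aldh1l2, a mitochondrial folate enzyme, had 4 counts in total in the libraries labelled WT and a mean of 9.12 CPM in those labelled Mll5+/-. Septin9 and Zkscan2 had no count in any library labelled WT, and had 9.94, 1.83 and 1.70 CPM and 3.35, 7.37 and 1.23 CPM in those labelled Mll5+/-. Unadjusted p-values of these genes in edgeR ran from 0.00257 to 0.00557, and none passed the adjustment in edgeR. In DESeq2, Aldh1l2 (adjusted p = 0.00184), Tnpo3 (0.00635), Septin9 (0.00923), Zkscan2 (0.0134) and Tmem19 (0.0472) passed. Rere, Cinp and Selenoi did not.

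In the direction of lower levels, Shisa4, Gja1, Samsn1, Lonp2, Pphln1 and Galnt4 were also among the genes of smallest p. Shisa4 had no count in any library labelled Mll5+/-, and had 4.14, 4.12 and 11.1 CPM in those labelled WT. Gja1, the gap junction protein connexin 43, had 3.99 ± 2.51 against 24.9 ± 3.24 CPM (SD, n = 3 each). Samsn1, an adaptor of immune cells, had 106 ± 21.5 against 200 ± 15.1 CPM (SD, n = 3 each). Lonp2, a peroxisomal protease, had 8.26 against 35.1 CPM, Pphln1 had 5.03 against 21.8 CPM, and Galnt4 had 1.71 against 14.7 CPM. Their unadjusted p-values in edgeR ran from 0.00176 to 0.00438, and none of these genes passed the adjustment in edgeR. In DESeq2, Shisa4 (adjusted p = 0.000328), Gja1 (0.0343) and Galnt4 (0.0492) passed, and Samsn1, Lonp2 and Pphln1 did not.

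Of the microglial gene groups, the homeostatic genes, which mark microglia at rest, held 4 members with unadjusted p under 0.05, all 4 at lower levels in the libraries labelled Mll5+/-. Gpr34, a lysophospholipid receptor, had 758 ± 159 against 1197 ± 99.2 CPM (SD, n = 3 each). Sparc, a matrix protein gene, had 8473 against 11866 CPM and Serpine2, a protease inhibitor, 321 against 430 CPM. P2ry12, the purinergic receptor that guides microglial processes, had 1115, 1232 and 1087 CPM against 4269, 1366 and 5499 CPM. Of the 25 members, 21 had negative log2 fold changes (median -0.17). The mean level of the list per library, as a log2 deviation, was -0.02, 0.17 and 0.29 in the libraries labelled WT and -0.01, -0.05 and -0.38 in those labelled Mll5+/-. The list did not pass (camera, adjusted p = 0.0892; adjusted p = 0.895 with an estimated correlation), nor did a single member adjusted over the list alone (edgeR, smallest adjusted p = 0.0972). It passed at the preset correlation with limma-voom (camera adjusted p = 0.0163), and over the left-out libraries the adjusted p ran from 0.0553 without WT replicate 1 to 0.675 without WT replicate 3.

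The cytosolic ribosomal protein genes were the 1 list of 29 to pass, at higher levels in the libraries labelled Mll5+/- (82 members, median log2 fold change 0.29, camera adjusted p = 0.000318). The call was lost with an estimated correlation (adjusted p = 0.895). Of the 82 members, 66 had positive log2 fold changes and 0 had an unadjusted p under 0.05. Rps19 had 30.3 ± 5.70 against 15.4 ± 5.67 CPM and Rpl37 had 25.5 ± 6.05 against 12.8 ± 3.57 CPM (SD, n = 3 each). The mean ribosomal protein level per library, as the log2 deviation from the mean of all 6, was -0.60, -0.22 and 0.36 in the libraries labelled WT and -0.02, 0.36 and 0.12 in those labelled Mll5+/-. Without WT replicate 1, the adjusted p was 0.922, without WT replicate 2 it was 0.0568 and without Mll5+/- replicate 2 it was 0.0662 (camera).

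The lists for the pathway in the title and for phagocytosis did not pass. In the list of TREM2, PI3K, SGK and GSK3 signalling, 3 of 28 members had an unadjusted p under 0.05, all at lower levels in the libraries labelled Mll5+/-, among them Sgk3 and Sgk1. Sgk3 was the 1 member to pass adjusted over the list alone (edgeR adjusted p = 0.00465), a list that was built around the genes the study named. Its median was 0.06 and its mean 0.01, while the camera test pointed down (adjusted p = 0.844). Among phagocytic receptors and engulfment genes, Cdc42 had 295 against 419 CPM and Rac1 1540.2 against 959 CPM, both small GTPases of the actin machinery (median 0.01, camera adjusted p = 0.734). The same 2 genes led the list of actin, migration and process motility (median 0.10, adjusted p = 0.734).

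Other microglial states showed no list past the threshold in the main camera test. The disease-associated genes had a median of -0.01 (adjusted p = 0.844), with Ank at 11.7 against 27.7 CPM and the chemokine gene Ccl6 at 105 against 171 CPM. Complement and synaptic pruning genes had a median of -0.06 (adjusted p = 0.734), led by P2ry12. Inflammatory cytokines and NF-kB targets had a median of 0.10 (adjusted p = 0.734), with Tlr2 at 15.8 against 5.53 CPM and Il1b without a count in the libraries labelled WT and at 0.671, 2.14 and 0.945 CPM in those labelled Mll5+/-. Type I interferon response genes had a median of 0.21 (adjusted p = 0.963), while fry pointed down, with Cxcl10 at 0.955 against 7.42 CPM and Usp18 at 42.5 against 25.5 CPM. Without Mll5+/- replicate 2, the interferon list passed at the preset correlation in the direction of lower levels (camera adjusted p = 0.0144). With all 6 libraries, its adjusted p was 0.990 with an estimated correlation (camera). Antigen presentation genes had a median of 0.21 (adjusted p = 0.734), with Pdia3 at 224 against 311 CPM and Erap1 at 20.5 against 37.6 CPM.

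Lysosome genes had a median of -0.06 (camera adjusted p = 0.844), with Ctsa at 111 against 63.1 CPM and Atp6v0b at 394 against 300.0 CPM. Autophagy genes had a median of 0.01 and a negative mean (adjusted p = 0.844), with Gabarapl1 at 18.9 against 5.69 CPM and Wipi1 at 8.10 against 16.7 CPM. Unfolded protein and integrated stress response genes had a median of -0.29 (adjusted p = 0.0962). Among them, the chaperone gene Hspa5 had 445 against 586 CPM and Eif2ak3 21.4 against 11.4 CPM. The list passed at the preset correlation without Mll5+/- replicate 2 (camera adjusted p = 0.0106). Its member Canx had 136 and 140.2 CPM in Mll5+/- replicates 1 and 3 and 3476 CPM in replicate 2. How far Canx carried that pass was not tested. Cell cycle genes had a median of -0.30 (adjusted p = 0.330), with Rrm1 at 31.3 against 7.63 CPM and Ccne2 at 6.49 against 17 CPM. TGF-beta signalling genes had a median of -0.01 (adjusted p = 0.734), with Smad2 at 11.8 against 21.9 CPM and Tgfb1 at 1.67 against 6.02 CPM, and passed at the preset correlation without Mll5+/- replicate 1 (camera adjusted p = 0.0339). With all 6 libraries, the stress response and TGF-beta lists both had an adjusted p = 0.895 with an estimated correlation (camera). Genes of the Wnt and beta-catenin pathway had a median of 0.03 (adjusted p = 0.734), with Btrc at 14.4 against 4.01 CPM and Lrp6 at 137 against 109 CPM.

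Metabolic lists did not pass either in camera. Nuclear-encoded oxidative phosphorylation genes had a median of 0.07 (adjusted p = 0.734), with Atp5g1 at 18.1 against 6.99 CPM and Uqcrq at 3.41 against 12.8 CPM. Glycolysis and hypoxia genes had a median of 0.03 and a negative mean (adjusted p = 0.922), with Bnip3l at 299.9 against 383 CPM and Slc2a3 at 0.481 against 4.48 CPM. Cholesterol genes had a median of -0.14 while the test pointed up (adjusted p = 0.922), with Nsdhl at 1.59 against 7.99 CPM and Ebp at 7.84 against 3.12 CPM. Lipid handling genes had a median of -0.06 and a mean of 0.34 (adjusted p = 0.856), with Cd36 at 4.38 against 0.368 CPM and Pnpla2 at 13.1 against 5.11 CPM.

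Relatives and partners of MLL5 and the H3K4 methylation machinery had a median of -0.02 and a mean of 0.06 (camera adjusted p = 0.876), with Kmt2a at 235 against 334 CPM and Setd1a at 11.8 against 4.67 CPM. Autism-associated genes had a median of 0.00 and a negative mean (adjusted p = 0.856). Of their 49 tested members, 5 had an unadjusted p under 0.05, all at lower levels in the libraries labelled Mll5+/-. Among them Naa15, an N-terminal acetyltransferase subunit, had 88.7 ± 2.18 against 136 ± 20.8 CPM (SD, n = 3 each). None passed in edgeR when adjusted over the list alone.

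**Figure D2:**
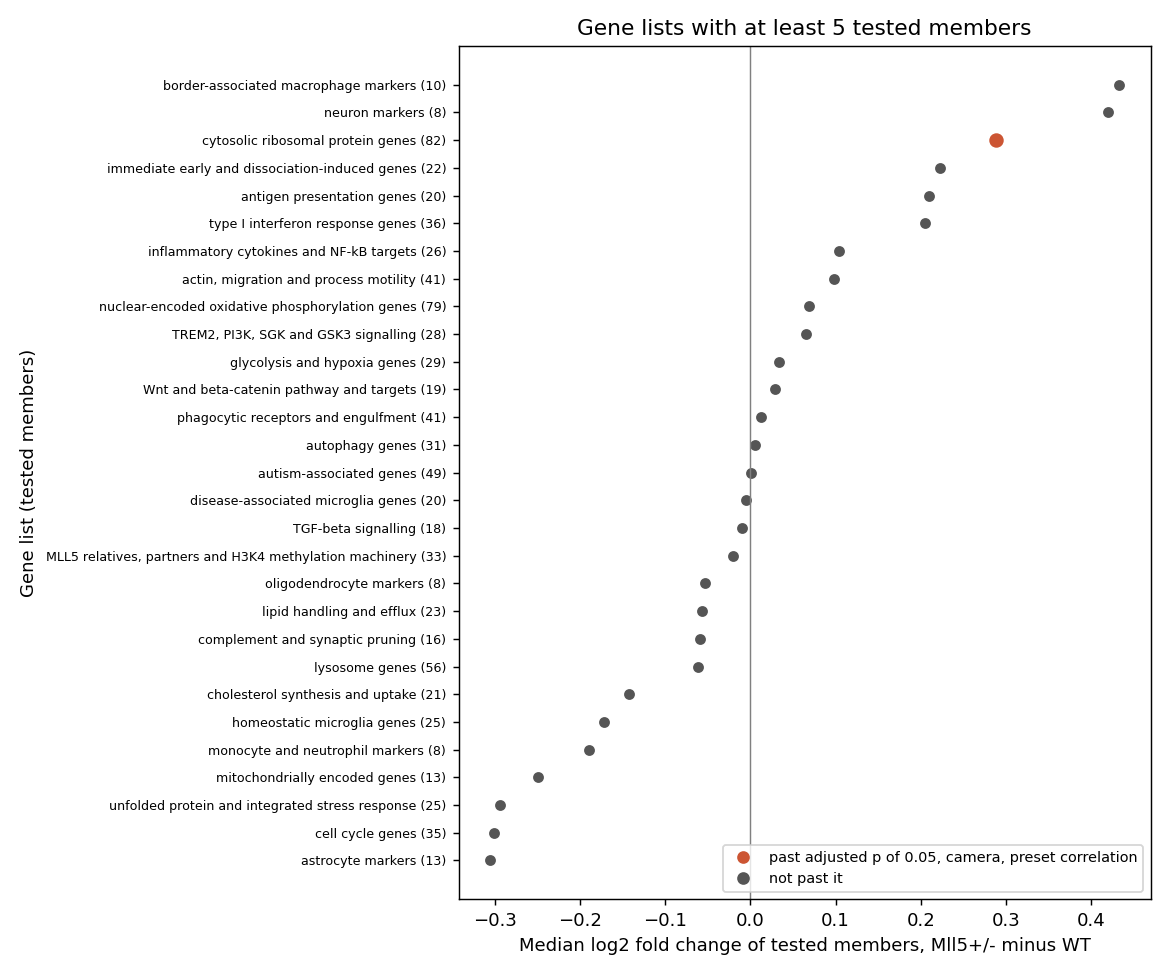
Median log2 fold change, labelled Mll5+/- minus labelled WT, of the tested members of each list with at least 5 of them, with member numbers in parentheses. The ribosomal protein list, at 0.29, is the 1 list past the threshold at the preset correlation, and its call was lost with an estimated correlation (adjusted p = 0.895).

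Markers of other cell types were looked at by list. Astrocyte markers had a median of -0.31 (camera adjusted p = 0.0892; adjusted p = 0.895 with an estimated correlation). At the preset correlation, the list passed with 1 surrogate variable (camera adjusted p = 0.00462) and without Mll5+/- replicate 3 (0.00758). Of the 13 tested, Gja1 passed adjusted over the list alone (edgeR adjusted p = 0.0325), and Plpp3 had 4.47 against 16.7 CPM. Slc1a3, the most abundant astrocyte marker, had 323 ± 119.9 against 391 ± 101 CPM (SD, n = 3 each). Neuron markers had a median of 0.42 (adjusted p = 0.734), with Sox11 at 17.6 against 4.30 CPM and Snap25 at 19.1 against 11.3 CPM, while the most abundant, Rtn1 and Prox1, had 128 against 153 CPM and 27.4 against 37.6 CPM. Oligodendrocyte markers had a median of -0.05 (adjusted p = 0.734), with Cldn11 at 2.02 against 11 CPM.

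Border-associated macrophage markers had a median of 0.43 (camera adjusted p = 0.330), with Mrc1 at 149.7 against 94.5 CPM and Stab1 at 327 against 201 CPM. Monocyte and neutrophil markers had a median of -0.19 (adjusted p = 0.734), with Csf3r at 219.8 against 194 CPM and S100a9 at 7.53, 0 and 26.5 CPM in the libraries labelled WT and 0, 6.18 and 0 CPM in those labelled Mll5+/-. Lists of lymphocyte, erythrocyte and platelet, endothelial and mural, oligodendrocyte progenitor and ependymal markers had fewer than 5 tested members and were not tested. Among these, Il7r had 157 against 203 CPM, Ttr ran from 0 to 122 CPM over the 6 libraries, Pecam1 had 13.1 against 7.27 CPM and Ptprz1 had 2.28 against 5.25 CPM, and 0 erythrocyte or platelet markers passed the low-count filter. Immediate early and dissociation-induced genes had a median of 0.22 (adjusted p = 0.734), with Atf3 at 7.88 against 2.50 CPM and Junb at 47.9 against 33.9 CPM. Mitochondrially encoded genes had a median of -0.25 (adjusted p = 0.256), with mt-Cytb at 1020.4 against 1524 CPM and mt-Nd2 at 2169.6 against 2817 CPM. Their share of counts was 2.90%, 2.56% and 2.89% in the libraries labelled WT and 2.09%, 1.88% and 3.55% in those labelled Mll5+/-. At the preset correlation, the list passed in the direction of lower levels with limma-voom (camera adjusted p = 0.00120), with 1 surrogate variable (0.00126) and without Mll5+/- replicate 3 (0.000582). With all 6 libraries in edgeR, its adjusted p was 0.895 with an estimated correlation.

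Libraries of 1 genotype were no closer to each other than libraries of different genotypes. The mean Pearson correlation of log2 CPM over tested genes, which are not independent replicates, was 0.80 ± 0.0275 (SD, 6 pairs) within genotypes and 0.804 ± 0.0286 (SD, 9 pairs) between them. The first principal component of the 500 most variable genes (28.4% of the variance) set Mll5+/- replicate 3 apart from the other libraries. That library had a count for 10487 genes, and the others for 10684 to 11040 genes after thinning all to the size of the smallest.

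Several abundant genes, chosen after their values were seen, were at far lower levels in some libraries of a genotype than in others. Lrrc8a, a subunit of volume-regulated anion channels, had 1.80, 1959 and 2061 CPM in the libraries labelled WT and 1869, 0.176 and 1835 CPM in those labelled Mll5+/-. Zfp691 had 0.913 CPM in Mll5+/- replicate 2 and at least 1845 CPM in the other libraries. Canx, an endoplasmic reticulum chaperone, had 136 and 140.2 CPM in Mll5+/- replicates 1 and 3 and at least 3476 CPM in the other libraries. Wtap, a subunit of an RNA methyltransferase complex, had at most 39.4 CPM in 4 libraries and 1834 and 2445 CPM in WT replicates 2 and 3. Septin2, a cytoskeletal GTPase, had 2725, 3054 and 13.7 CPM in the libraries labelled WT and 16.4, 3205 and 21.3 CPM in those labelled Mll5+/-.

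**Figure D3:**
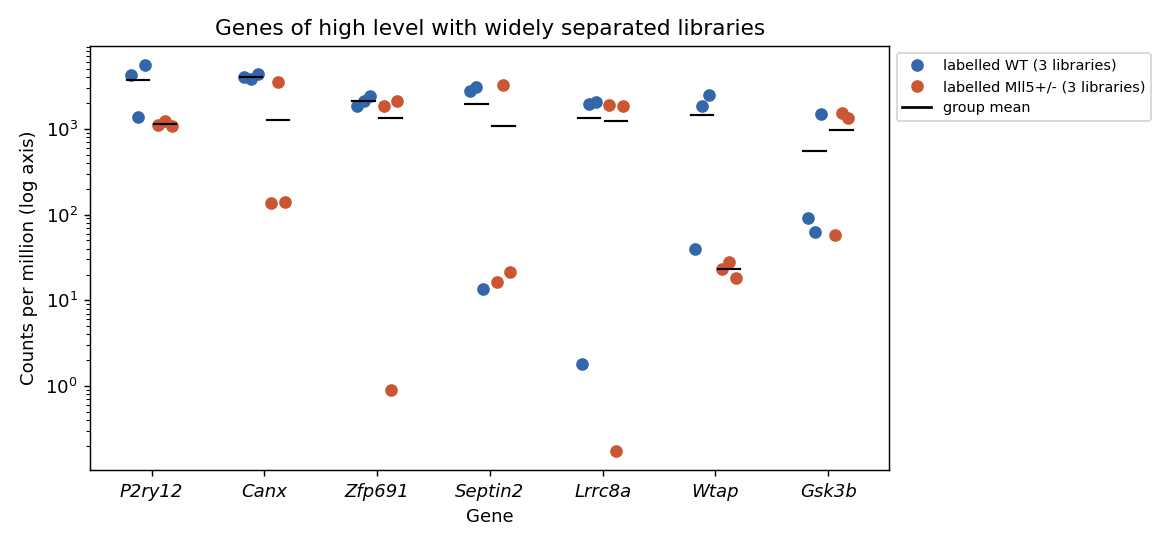
CPM on a log axis for abundant genes with widely separated libraries, 1 point per library, with a bar at each group mean. Within 1 genotype, libraries of Gsk3b, Canx, Septin2 and Lrrc8a differ over 16-fold, while those of P2ry12 differ less.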

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

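No alternative was chosen after the result was seen. Of 1116 values recomputed for 80 genes, 1100 kept their direction and their side of the threshold and 14 passed it with the same direction. The other 2 are of Kmt2e, whose log2 fold change ran from -0.36 to 0.18 over the left-out libraries. It turned positive without WT replicate 3 (0.18) and without Mll5+/- replicate 2 (0.16). As no gene passed in the main test, no call could be lost, so the counts of recomputed values bear on direction at most. Genes past 0.05 numbered 0 in the main edgeR test, 29 in DESeq2, 1 with a surrogate variable (Zfp62), between 0 and 2 with a library left out, and 229 by an unadjusted p under 0.05 with an absolute log2 fold change of at least 1. Leaving out single libraries brought calls of Wtap and Nectin4 (without WT replicate 1), Mier3 and P2ry12 (without WT replicate 2), Canx (without Mll5+/- replicate 2), and Atp2c1 and Zfp62 (without Mll5+/- replicate 3). The cause was not tested. The count under an unadjusted p of 0.05 ran from 293 to 565. Sgk3 passed in DESeq2 (log2 fold change -2.23, adjusted p = 0.000111), which gives 1 title gene past 0.05, and kept a log2 fold change between -2.44 and -2.14 over its alternatives, with adjusted p from 0.000111 to 0.99998. Title genes past 0.05 adjusted over the list alone numbered between 1 and 2 with a library left out, with 2 without Mll5+/- replicate 1. Lists past 0.05 numbered 1 in the main test, 3 with limma-voom (homeostatic, mitochondrially encoded, ribosomal protein), 3 with a surrogate variable (mitochondrially encoded, astrocyte, ribosomal protein), 0 with an estimated correlation, 0 with fry and between 0 and 3 with a library left out (the highest without Mll5+/- replicate 3). The adjusted p of the ribosomal protein list was 0.895 with an estimated correlation, 0.797 with fry, and from 2.47e-13 to 0.922 with a library left out. The difference between the mean correlations within and between genotypes stayed under the spread between pairs with Spearman correlations (-0.002). Values were not available for Il1b with the CPM filter, or for mt-Cytb, mt-Nd2 and Sparc when the genes themselves were left out. At 21075570 counts or more per library, depth may limit genes of few counts, such as Gsk3a, with at most 63, which was not tested.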

Other observations

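The tests of a single deviating library for Sgk3, of ribosomal protein genes varying together, of the loss of scarce transcripts and of 2 levels were chosen only after the result was seen.

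Sgk3 was at a lower level in the 3 libraries labelled Mll5+/-. A single deviating library is argued against, since the log2 fold change nearest 0 with each library left out in turn was -2.14. Reads credited to a neighbouring gene are argued against for listed genes, since Mcmdc2, the 1 listed gene within 20 kb, gained far less than Sgk3 lacked. By total counts, Mcmdc2 had 3.56, 5.33 and 4.37 CPM in the libraries labelled WT and 5.39, 11.4 and 7.31 CPM in those labelled Mll5+/-. Its lowest Mll5+/- value exceeded its highest WT value by 0.0611 CPM. Sgk3 lacked 44.6 CPM between the group means, and unlisted transcripts stay open. Of the 10 splits of the 6 libraries, 10 had a smallest p at least as small as that of Sgk3 (0.000166, against 5.12e-10 for Septin2 in another split), and with 10 splits a share under 0.05 cannot be reached. A difference by genotype stays open. The level of Kmt2e did not bear out the labels, and with the disrupted part not given it could not refute them.

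Ribosomal protein genes were higher in the libraries labelled Mll5+/- by 0.31 on the log2 scale, within a range of 0.95 among the libraries labelled WT. The adjusted p was 0.922 without WT replicate 1, so 1 deviating library may account for the call. Libraries that vary in these genes together, whatever the genotype, are another candidate explanation, with p = 0.437 for an estimated correlation. As many lists as in the real split (1) passed in 9 of the 10 splits, with 6 as the highest other, and a share under 0.05 cannot be reached. A difference by genotype stays open.

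Of the tested genes, 1020 (9.42%) had counts at least 16-fold apart between libraries of 1 genotype and at least 10 CPM in their highest library. Values under 3 counts were first set to that level. Scarcer genes, under 10 CPM in every library, were not counted even where their libraries lie as far apart. Loss of scarce transcripts in amplification is argued against as the whole cause, since 3.60% of the 2000 most abundant genes (95% interval 2.87% to 4.51%) showed such a jump. Reads credited to an overlapping listed gene were predicted to show as an opposite overlapping gene for most of the 1020 genes. Of these genes, 16.96% overlap a listed gene at all, against 19.8% of matched genes. The prediction could thus not be met, and its test gives no verdict. That share does leave most of these genes without a listed gene to overlap. An opposite overlapping listed gene was met for 4.22% against 4.02% of matched genes, a difference of 0.196 percentage points (-1.53 to 1.92). For the genes that do overlap, and for unlisted transcripts, this explanation stays open. A transcript model counted in some libraries and not in others may give 2 levels. Over the 72 such genes among the 2000 most abundant, the largest gap took a median of 77.3% of the range. Simulated sets of normal values with the same SD and jump gave 40.0% to 46.6%. Any library far from closely similar others exceeds such sets, whatever the cause, so the excess does not decide between causes. The test cannot tell counting from expression that is on or off, a loss in 1 library (30 of 72 genes) also gives a large gap, and no biological explanation was tested.

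As many genes past an adjusted p of 0.05 as in the real split (0 in edgeR, with 312 under an unadjusted p of 0.05, 29 called by DESeq2 and 0 by limma-voom) were met in 10 of the 10 splits, with 8 as the highest other, which a real count of 0 fixes beforehand and which therefore tests nothing. As many genes under an unadjusted p of 0.05 were met in 7 of the 10, with 600 as the highest other. A share under 0.05 cannot be reached with 10 splits.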
